A study of Mus musculus with 6 samples.

How the data were processed

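RNA abundance was measured in C2C12 mouse myoblasts on 6 Affymetrix arrays, 3 of untreated cells and 3 of cells given 10 µM 5-azacytidine (5AC) for 3 days, and the groups and replicate numbers were taken from the sample labels. The authors deposited 1 table of processed probe-set intensity values on a linear scale, 1 column per array. GCOS 1.4 and R 2.4.1 are named per the submitters' processing notes, with no role; the summarization, background and normalization methods are not given in the sources used here. Array medians of 20.36 to 21.04 show that the columns were at a similar level, and 2.42% to 2.59% of the values on each array were below 0. Whether a scaling step made the levels similar is not known. Detection calls were not used here, so levels near background cannot be told from absence of RNA.

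The table held 45101 probe sets, of which 64 were controls. The platform annotation table paired 34945 with 1 gene symbol and 932 with several, and 9160 were unnamed here; 34741 of the 34945 matched the RefSeq gene table (assembly GRCm38.p6) by Entrez number, and 0 symbols needed an update. That table was used only for names and for which genes neighbour each other. Each of the 18193 genes was represented by its probe set with the highest mean over the 6 arrays; 9010 genes had more than 1 probe set. Among 3225 changed genes with several probe sets, 132 had a probe set past the threshold in the opposite direction.

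The design fixed in advance foresaw log2 values, or log2(value + 1) for a linear table, but not values below 0. Values below 0 were therefore set to 0 before log2(intensity + 1), a step chosen after seeing the data; 873 genes had a value at or below 0 on an array. A log2 change is on this scale: for dim genes it depends on the offset and on the floor. The change with 16 added is given beside log2 changes of genes with a group mean below 20.8, the median probe-set mean, in the text.

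Differences, 5AC minus untreated, were tested two-sided with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05; the prior degrees of freedom were 1.21. A size limit of 2-fold was applied as well. Gene lists, 38 in number and fixed before the data were examined, held 1235 genes, of which 1147 were measured. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and with fry beside it. An estimated correlation from 6 arrays is itself imprecise. With it, camera also takes its degrees of freedom from the arrays, far fewer than it takes from the genes with the preset correlation. A p for a measure of few arrays is from an exact permutation test.

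The genes named were set by a rule written beforehand: the 15 largest increases and 15 largest decreases past the threshold without overlap between groups, up to 4 members with the largest change past the threshold per list (where none passed, the 1 with the largest change), and Dnmt1, Dnmt3a, Dnmt3b, Uhrf1, Myod1, Myf5, Myog, Mef2c, Cdkn1a, Actb and Gapdh. Clone and predicted names were passed over for 2 increases and 1 decrease. The rule gave 175 genes; Gapdh had no probe set with 1 gene symbol and is given only through its control probe sets.

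The procedure was tested on simulated data with 18193 genes, 200 of them changed. It recovered 21.2% of genes changed by 0.5 on the log2 scale, 43.3% of those changed by 1 and 71.6% of those changed by 2, and 3 of its 94 calls were false. With no change simulated it called 0 genes and 0 lists. The simulated noise was independent between genes, so this does not test list calls where members are correlated. The share of genes changed was far below the 29.3% called in the data, so the recovery there may differ. Alternatives tried were quantile normalization, median centring, a replicate block, a limit on dim genes, other probe-set rules, an intensity trend, robust moderation, array weights, an offset of 16, a stricter threshold, a test against 1.5-fold, leaving out each array, and, added after seeing the data, leaving out genes with values at or below 0.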

Results

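RNA was measured in C2C12 cells, a mouse myoblast line whose cells divide as myoblasts and can fuse into muscle fibres. Cells seeded at 1500 per square centimetre grew for 3 days with or without 10 µM 5-azacytidine (5AC), a cytidine analogue that is built into nucleic acids and traps DNA methyltransferases, so that DNA methylation is lost as cells divide. Total RNA of day 3 was hybridised to 6 Affymetrix GeneChip mouse genome arrays, 3 from untreated and 3 from treated cultures. The median deposited intensity was 20.36 to 21.04 per array and the mean 165.0 to 168.8, and their number limits the precision. Correlations of log2 values over all probe sets were 0.965 to 0.971 between arrays of 1 group and 0.949 to 0.954 between arrays of different groups. Among the brighter probe sets the median absolute log2 difference was 0.099 to 0.123 within groups and 0.288 to 0.304 between groups. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical.

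The comparison asks which transcripts differ after 5AC. Treated cells had more RNA of the simple-epithelium keratins Krt8 and Krt18, of 25 of 54 germline genes, 30 of 47 sarcomere genes and 21 of 36 p53 target genes, and less RNA of 41 of 45 mitosis, 35 of 44 DNA replication and 18 of 20 cholesterol synthesis genes. As sets these 6 lists passed with a preset correlation but not with an estimated correlation (adjusted p = 0.0706 to 0.182 with an estimated correlation). For germline genes and p53 targets the estimate, -0.016 and 0.0065, was below the preset 0.01, so a higher correlation did not end their calls. For the others it was 0.12 to 0.41. The fewer degrees of freedom that camera uses with an estimate bear on all 6 lists. Krt8 rose from an intensity of 15.9 ± 2.16 to 1991 ± 114 (mean ± SD, n = 3 each), a log2 change of 6.89 ± 0.11 (SE; 5.98 with 16 instead of 1 added before the log). Nefl, which encodes the neurofilament light chain, fell from 1446 ± 61.9 to 130.0 ± 16.4, a log2 change of -3.47 ± 0.11. Of 18193 genes tested, 2821 were higher and 2512 lower in 5AC (limma, adjusted p under 0.05), 29.3% of the genes. With any single array left out, 1841 to 2475 were higher, the fewest without 5AC replicate 1. At least 2-fold changes numbered 559 higher and 377 lower, and at least 4-fold changes 135 higher and 39 lower. With 16 instead of 1 added before the log, 467 instead of 936 genes passed the 2-fold limit, 466 of them among the 936.

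**Figure D1:**
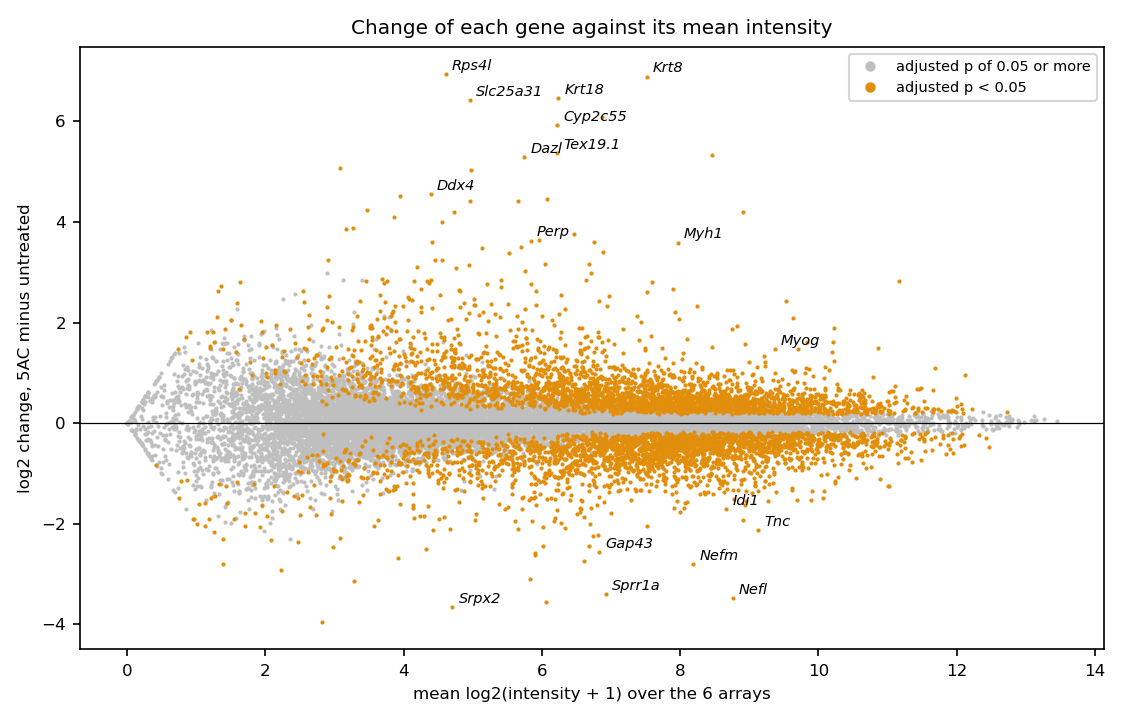
Each point is 1 of the 18193 genes: its mean log2(intensity + 1) over the 6 arrays (horizontal) against its log2 change, 5AC minus untreated (vertical), with genes of adjusted p under 0.05 in orange. Krt8 lies at a log2 change of 6.89 and Nefl at -3.47.

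The increases at the head of the ranking began near background. Rps4l, which encodes a ribosomal protein S4 paralogue, went from an intensity of 1.27 ± 0.61 to 268.4 ± 10.7 (log2 change 6.93 ± 0.23, or 4.04 with 16 added before the log). Krt18, the partner of Krt8, had a log2 change of 6.47 ± 0.48 (4.93 with 16 added). Cyp2c55, a cytochrome P450, rose by 5.93 ± 0.24 (4.59), Spinkl by 5.04 ± 0.17 (3.24), Dcaf8l by 4.45 ± 0.11 (3.49) and Trap1a by 4.42 ± 0.17 (2.87). Gramd1c rose by 4.52 ± 0.74 and by 2.22 with 16 added. The 15 increases named, chosen for passing the threshold without overlap between groups, had adjusted p from 0.000103 for Krt8 to 0.00965 for Gramd1c.

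Among the decreases, Srpx2 fell from 91.9 ± 5.94 to 6.40 ± 1.21 (log2 change -3.66 ± 0.14, -2.27 with 16 added), Stmn4, of the stathmin family, had a log2 change of -3.55 ± 0.26 (-2.80 with 16 added), and Sprr1a, a cornified-envelope protein, had a log2 change of -3.41 ± 0.06. Alox5ap, needed for leukotriene synthesis, had a log2 change of -3.09 ± 0.12 (-2.39 with 16 added), Ccbe1 of -2.75 ± 0.15, Mgam of -2.59 ± 0.08 and the Wnt antagonist Dkk2 of -2.50 ± 0.28 (-1.41 with 16 added). Exosc6, an exosome subunit, had mean intensities of 27.0 ± 4.16 untreated and -2.41 ± 6.38 treated, so its log2 change of -3.95 ± 0.75 rests on the floor at 0 and was -1.29 with 16 added. Lingo2 and Lmcd1 were also dim, with log2 changes of -3.14 and -2.93 that were -1.23 and -0.72 with 16 added. The calls of Exosc6 and Lmcd1 were lost when single arrays were left out. Sbsn had a log2 change of -2.68 (-1.34 with 16 added), while a probe set of it without a suffix gave 1.01.

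Among germline genes, those past the threshold were all higher. Of 54 measured genes of the list of germline genes silenced by DNA methylation, 25 were higher, 0 lower and 29 not past the threshold, and 27 were higher when adjusted over the list alone; the median log2 change was 0.92 (0.32 with 16 added). Slc25a31, the testis-type ADP/ATP carrier, rose from 2.89 ± 2.66 to 286.6 ± 7.56, Tex19.1, which restrains retrotransposons in germ cells, from 10.8 ± 3.13 to 479.2 ± 43.2, and Dazl, a germ-cell RNA-binding protein, from 7.67 ± 1.82 to 335.8 ± 28.0. Mael, of the piRNA pathway, had a log2 change of 5.06 ± 0.38 that was 1.94 with 16 added. Ddx4, Taf7l and Tex12, also germline genes, rose by 4.55 ± 0.12, 4.41 ± 0.21 and 4.23 ± 0.66, values that were 2.59, 3.24 and 1.80 with 16 added. The set test gave adjusted p = 6.52e-08, and adjusted p = 0.0706 with an estimated correlation.

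**Figure D2:**
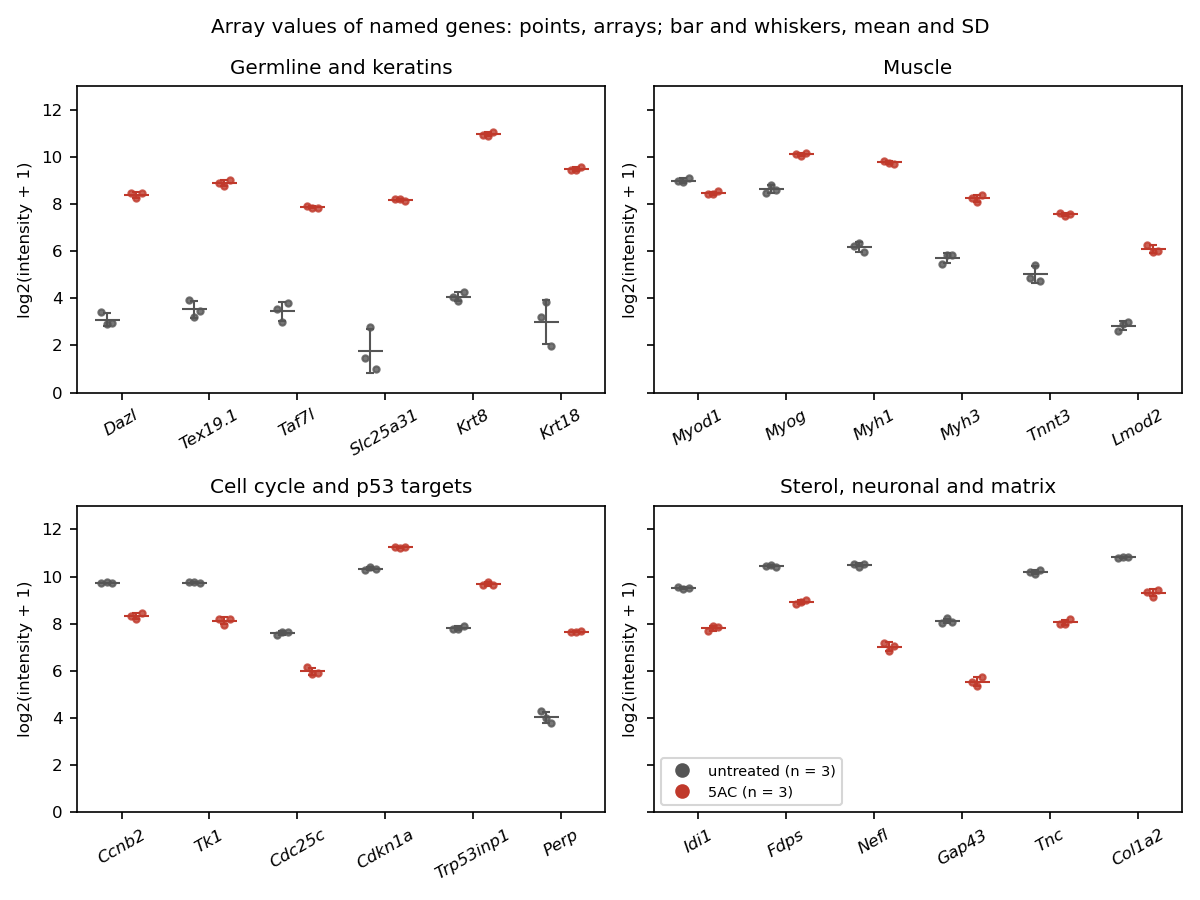
Log2(intensity + 1) of named genes on each array: points are arrays (grey untreated, red 5AC, n = 3 each), and the bar and whiskers are their mean and SD. Krt8 and Krt18, named by a rule that asks for no overlap between groups, have log2 changes of 6.89 and 6.47, while Myod1 differs by -0.54.

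Genes of the contractile apparatus were more often higher than lower. Of 47 measured sarcomere and contractile genes of skeletal muscle, 30 were higher, 2 lower and 15 not past the threshold, with the same numbers, 30 and 2, adjusted over the list alone, and 26 rose at least 2-fold. The median log2 change was 1.13 (0.78 with 16 added), and the set test gave adjusted p = 2.27e-09, with adjusted p = 0.182 with an estimated correlation. Embryonic myosin heavy chain Myh3 rose from 51.6 ± 7.67 to 301.7 ± 30.1 (log2 change 2.53 ± 0.14), fast troponin T Tnnt3 by 2.54 ± 0.19 and Lmod2, an actin nucleator, by 3.24 ± 0.13 (1.90 with 16 added). Adult fast myosin Myh1 rose by 3.59 ± 0.12, while its probe set without a suffix gave -0.25. Of 32 genes for excitation-contraction coupling and neuromuscular receptors, 12 rose and 4 fell (13 and 4 adjusted over the list alone), among them Srl, by 1.81 ± 0.19, and the fetal acetylcholine receptor subunit Chrng, by 1.74 ± 0.22. As a set these did not pass (adjusted p = 0.178).

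The myogenic transcription factors went both ways. Myog, which drives terminal differentiation, rose from 397.1 ± 49.1 to 1100.5 ± 51.1 (log2 change 1.47 ± 0.11, adjusted p = 0.00104). Myod1 fell from 507.6 ± 33.8 to 348.7 ± 17.1 (-0.54 ± 0.08, adjusted p = 0.00589), and Msc, a repressor of MyoD activity, and Eya1 fell by 1.71 and 0.91. Myf5 had a log2 change of -0.25 ± 0.11 (adjusted p = 0.153) and Mef2c of -0.07 ± 0.14 (adjusted p = 0.767). In all, 3 of 15 were higher and 4 lower, also adjusted over the list alone (set test adjusted p = 0.310). Of 26 genes for myoblast fusion and adhesion, 3 rose and 10 fell (3 and 12 adjusted over the list alone). The fusion protein gene Mymk rose by 1.57 ± 0.08 and Jam2, an adhesion molecule, fell by 1.35. Their median log2 change was -0.18 and their mean 0.07, so the signs differ; the set test gave adjusted p = 0.0410, downward, and adjusted p = 0.333 with an estimated correlation. This call was also lost with quantile normalization, other probe-set rules and an offset of 16. Of 20 genes of muscle energy metabolism, 5 rose and 4 fell (7 and 4 adjusted over the list alone), among them muscle phosphoglycerate mutase Pgam2, by 1.75 ± 0.07, or 1.13 with 16 added (set test adjusted p = 0.698).

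Cell division genes past the threshold were all lower in these lists. Of 45 mitosis genes, 0 were higher, 41 lower and 4 not past the threshold, and 43 were lower adjusted over the list alone, with a median log2 change of -0.73. Cyclin B2, Ccnb2, went from 850.5 ± 7.84 to 324.5 ± 28.7, the phosphatase gene Cdc25c from 193.7 ± 10.6 to 62.3 ± 6.60 and the centromeric histone gene Cenpa from 979.5 ± 17.8 to 426.6 ± 15.8. The set test gave adjusted p = 1.79e-21, and adjusted p = 0.182 with an estimated correlation. Of 44 DNA replication and S phase genes, 35 were lower, 0 higher and 9 not past the threshold (38 lower adjusted over the list alone), with thymidine kinase Tk1 at -1.62 ± 0.09 and the replication helicase subunit Gins1 at -1.15 ± 0.09. Their set test gave adjusted p = 3.44e-14, and adjusted p = 0.0926 with an estimated correlation. Of 9 histone genes, 5 fell and 4 did not pass (7 lower adjusted over the list alone), with H2ax at -1.32 ± 0.06 and H2az1 at -0.89 ± 0.05; the set test gave adjusted p = 0.00158, and adjusted p = 0.0926 with an estimated correlation.

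**Figure D3:**
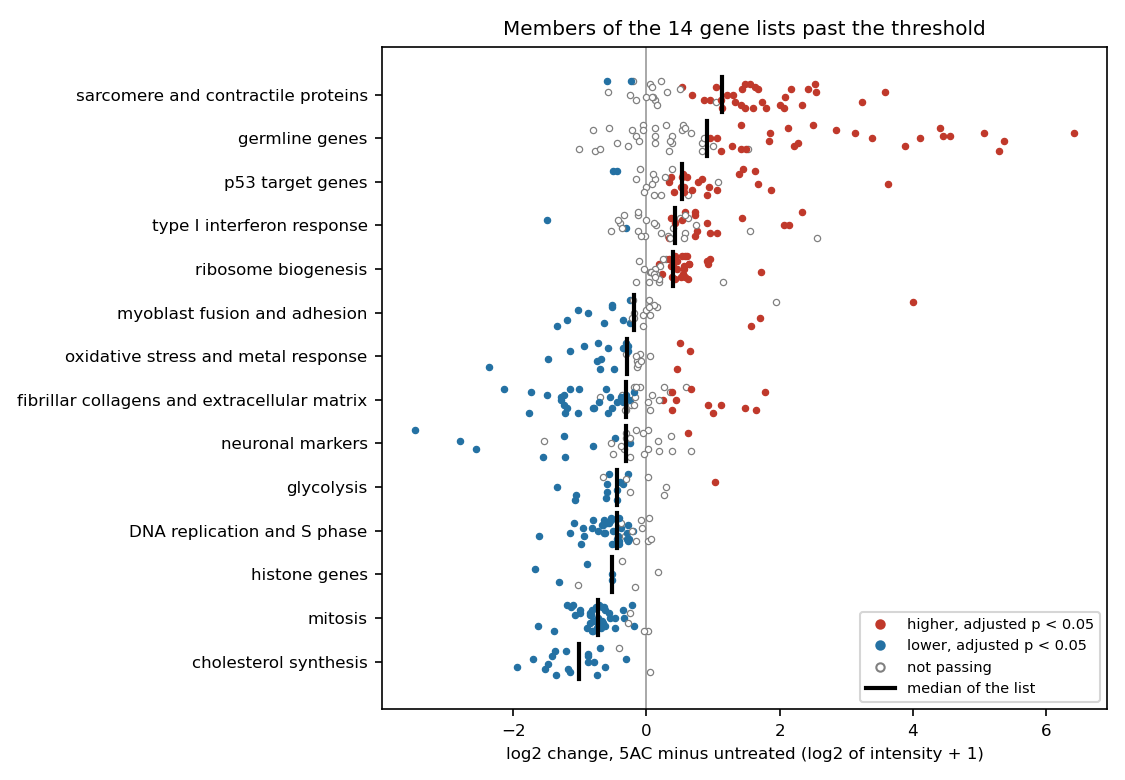
Log2 change, 5AC minus untreated, of every measured member of the 14 gene lists past the threshold with the preset correlation (0 with an estimated correlation): red and blue points are genes higher and lower at adjusted p under 0.05, open points did not pass, and the black bar is the list's median. Medians run from -1.02 for cholesterol synthesis to 1.13 for sarcomere and contractile proteins (-0.93 and 0.78 with 16 added before the log).

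Genes that p53 activates were more often higher than lower. Of 36 measured targets, 21 were higher, 2 lower and 13 not past the threshold (25 and 2 adjusted over the list alone), with a median log2 change of 0.54. The cyclin-dependent kinase inhibitor gene Cdkn1a went from 1294 ± 70.8 to 2427 ± 48.5 (0.91 ± 0.06), Perp, a desmosomal and apoptosis-related protein, from 15.5 ± 2.82 to 200.5 ± 2.76, and Trp53inp1 rose by 1.87 ± 0.07. Sulf2 rose by 1.67 ± 0.15, while its probe set without a suffix fell, at -0.57. The set test gave adjusted p = 4.48e-08, and adjusted p = 0.0706 with an estimated correlation. Ribosome biogenesis genes were higher in 25 of 41 cases, lower in 0 and not past the threshold in 16 (30 higher adjusted over the list alone), among them Noc3l, by 1.72 ± 0.17, and Nop14, by 0.96 ± 0.11. Their set test gave adjusted p = 2.27e-09, and adjusted p = 0.0926 with an estimated correlation.

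Genes for cholesterol synthesis, glycolysis and oxidative stress were more often lower than higher. Of 20 cholesterol synthesis genes, 18 were lower, 0 higher and 2 not past the threshold, with 18 lower adjusted over the list alone as well, and the median log2 change was -1.02. Isopentenyl diphosphate isomerase Idi1 went from 732.1 ± 17.6 to 223.7 ± 15.9, Pmvk had a log2 change of -1.94 ± 0.17 and Tm7sf2 of -1.47 ± 0.13. Their set test gave adjusted p = 6.57e-13, and adjusted p = 0.0926 with an estimated correlation. Of 19 glycolysis genes, 12 fell, 1 rose and 6 did not pass (12 lower and 3 higher adjusted over the list alone), with the glucose transporter Slc2a1 at -1.07 ± 0.06 and Pdk1 at -1.34 ± 0.13. Their set test gave adjusted p = 5.73e-05, and adjusted p = 0.0926 with an estimated correlation. Of 26 genes of oxidative stress and metal response, 14 fell, 3 rose and 9 did not pass (14 and 3 adjusted over the list alone), among them the glutathione enzymes Gpx3, at -1.48 ± 0.12, and Gstm1, at -1.15 ± 0.06; the set test gave adjusted p = 5.53e-05, and adjusted p = 0.197 with an estimated correlation.

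Matrix and neuronal genes fell more often than they rose. Of 54 genes for fibrillar collagens and extracellular matrix, 26 were lower, 11 higher and 17 not past the threshold, also 26 and 11 adjusted over the list alone. Tenascin C, Tnc, went from 1166 ± 59.0 to 265.7 ± 21.9 and Col8a1 from 468.9 ± 6.51 to 137.5 ± 11.8, while Col6a2 rose by 1.79 ± 0.29 (1.22 with 16 added). The set test gave adjusted p = 0.000741, and adjusted p = 0.333 with an estimated correlation. Of 29 neuronal markers, 9 were lower, 1 higher and 19 not past the threshold (10 and 1 adjusted over the list alone). They include the neurofilament gene Nefm, at -2.81 ± 0.08, the growth-cone gene Gap43, at -2.56 ± 0.12, and Stmn2, at -1.55 ± 0.07; the set test gave adjusted p = 0.00210, and adjusted p = 0.0926 with an estimated correlation. Of 43 type I interferon response genes, 16 rose, 2 fell and 25 did not pass (18 and 2 adjusted over the list alone). Bst2, which tethers virions, rose by 2.14 ± 0.14 and Igtp by 2.06 ± 0.33 (1.47 and 1.07 with 16 added), and Ifit2 fell by 1.50. Their set test gave adjusted p = 0.00462, and adjusted p = 0.0926 with an estimated correlation.

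Genes of the methylation machinery went both ways, with 4 of 24 higher and 6 lower (5 and 6 adjusted over the list alone, set test adjusted p = 0.698). The largest changes past the threshold were of Apobec2, at 1.66 ± 0.11, Idh1, at -1.55 ± 0.07, and Idh2, at -1.51 ± 0.06. These are members of the list but not DNA methyltransferases. A probe set of Idh2 without a suffix gave 0.12. The maintenance methyltransferase gene Dnmt1 fell from 333.8 ± 14.1 to 245.2 ± 4.0 (-0.44 ± 0.06, adjusted p = 0.00450) and its cofactor Uhrf1 fell by 0.62 on the log2 scale (adjusted p = 0.00191). Dnmt3a had a log2 change of 0.59 ± 0.18 (adjusted p = 0.0638) and Dnmt3b of -0.06 ± 0.14 (adjusted p = 0.810). Of 40 imprinted genes, 8 rose and 3 fell, also adjusted over the list alone (set test adjusted p = 0.261), with the growth factor gene Igf2 at 2.76 ± 0.17 (1.93 with 16 added) and Ndn at 1.19 ± 0.08. Nap1l5 was listed at or below 0 on all 3 untreated arrays and at a mean of 1.78 in 5AC; it is counted among those that rose, a call lost with 16 added (adjusted p = 0.0569). In the insulin-like growth factor pathway 6 of 17 rose and 2 fell, also adjusted over the list alone, among them Igfbp4, by 2.01 ± 0.14 (set test adjusted p = 0.310). Of 23 pluripotency genes 0 rose and 2 fell, Sox2 and Klf4, at -0.95 ± 0.12, or -0.63 with 16 added, and -0.27 ± 0.06 (0 and 1 adjusted over the list alone; set test adjusted p = 0.718), and the call of Klf4 was lost when single arrays were left out.

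Markers of other cell types were read as other lineages the cultures could hold. Of 31 epithelial markers 6 rose and 2 fell, also adjusted over the list alone (set test adjusted p = 0.261), with Krt14 at 2.14 ± 0.21 beside Krt8 and Krt18. The 2 that fell, named after their values were seen, were the keratin gene Krt19, from 439.0 ± 26.2 to 195.2 ± 15.2, and the desmosomal gene Pkp1, at -1.27 ± 0.05. Of 22 osteoblast markers 2 rose and 8 fell (3 and 9 adjusted over the list alone; adjusted p = 0.0594), Ogn rising by 1.89 ± 0.08 and Col1a2 falling by 1.49. Of 31 adipocyte markers 5 rose and 9 fell, also adjusted over the list alone (set test adjusted p = 0.190). Plin4 was at 1.31 ± 0.11 and Scd1 at -0.90 ± 0.05. Of 27 cartilage markers 2 rose and 3 fell (1 and 2 adjusted over the list alone, set test adjusted p = 0.917). Fmod was at 1.84 ± 0.26 (1.01 with 16 added) and Matn2 at -1.57 ± 0.11. Of 24 smooth muscle markers 8 rose and 5 fell (9 and 6, set test adjusted p = 0.698). Actg2 was at 1.12 ± 0.07 and Myh11 at -1.79 ± 0.37 (-0.32 with 16 added). Of 27 cardiac markers 2 rose and 1 fell (1 and 0, set test adjusted p = 0.935). Smpx, which skeletal muscle also expresses, was at 3.64 ± 0.14 (2.84 with 16 added). The other 24 did not pass, among them Nppa, Nkx2-5 and Myl7. Of 20 endothelial markers 2 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.879), with Ramp2 at 0.80 ± 0.09 (0.52 with 16 added). Of 26 macrophage and leukocyte markers 3 rose and 0 fell (1 and 0; adjusted p = 0.738), with Fcer1g at 2.82 ± 0.33 (1.52 with 16 added).

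Other stress and signalling lists did not pass as sets. Of 39 genes of the integrated stress response 14 rose and 11 fell (16 and 12 adjusted over the list alone; adjusted p = 0.718), with Ddit3, the transcription factor CHOP, from 231.5 ± 10.9 to 885.2 ± 30.8 and its target Trib3 at 1.88 ± 0.10. Of 32 unfolded protein response and chaperone genes 6 rose and 14 fell (10 and 15; adjusted p = 0.261), with Pdia4 at -1.21 ± 0.09 and Hsph1 at 0.65 ± 0.06. Of 36 inflammatory genes 3 rose and 10 fell (3 and 11; adjusted p = 0.108), with the cytokine genes Tslp at -2.62 ± 0.09 and Il33 at -2.08 ± 0.15. Of 20 antigen presentation genes 6 rose and 3 fell (8 and 3; adjusted p = 0.458), with H2-M3 at 1.20 ± 0.18, and of 32 complement and lysosomal genes 9 rose and 6 fell (10 and 7; adjusted p = 0.669), with C1ra at 1.29 ± 0.14 (0.48 with 16 added). Of 28 BMP and TGF-beta genes 9 rose and 4 fell (10 and 4; adjusted p = 0.352), with follistatin, Fst, at 1.49 ± 0.11 and Ccn2 at 1.11 ± 0.06. Of 23 Notch pathway genes 3 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.969). Jag1 was at 1.32 ± 0.06, the receptor gene Notch3 at -1.26 ± 0.10 and Hes1 at -0.78 ± 0.10. Of 51 oxidative phosphorylation genes 7 rose and 3 fell (5 and 1; adjusted p = 0.998), with Ndufb9 at 0.42 ± 0.05.

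Of 14 reference genes 2 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.310); Hprt had a log2 change of -0.60 ± 0.06 and Actb of 0.06 ± 0.05 (adjusted p = 0.453). Beside the lists above, the 3' minus 5' log2 difference of the Gapdh control probe sets was -0.27 ± 0.02 untreated and -0.11 ± 0.02 in 5AC (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give), and that of Actb 0.32 ± 0.03 and 0.40 ± 0.02 (exact permutation p = 0.1). Median, mean and test differed in sign for 8 lists: fusion and adhesion, integrated stress response, pluripotency, macrophage, cartilage, cardiac, Notch and oxidative phosphorylation. Of 38 lists, 14 passed with the preset correlation and 0 with an estimated correlation, while 32 passed fry's directional test. Unlike camera, fry does not compare a list with the other genes, and the reference genes passed it too (fry adjusted p = 0.0011).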

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

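The split of the arrays was tested as planned, and the probe sets below lie outside the comparison of named genes. Among the 9160 probe sets with no gene named here, 114 were higher and 92 lower at least 2-fold in 5AC at adjusted p under 0.05, and 37 and 5 at least 4-fold. Among the 932 with several genes named, 22 were higher and 23 lower at least 2-fold. They are given because the gene-level comparison does not use them; they went in both directions, and no explanation was tested for them.

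Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many as 5333 changed genes, and the highest of the other splits gave 1. For changes of at least 2-fold the real split gave 936 genes, again in 1 of the 10 splits, and the highest other gave 1. With 10 splits no share under 0.05 can be reached.

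In all, 8215 genes (45.2%) had no overlap between groups, where 3 against 3 gives 10% by chance, and 7207 genes had an unadjusted p under 0.05.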

How the results depend on the processing

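The alternative that leaves out genes with values at or below 0 was chosen after the data were seen. Of 170 named genes past the threshold, 127 stayed past it in the same direction under every alternative that tested them and 43 did not. Of these, 8 changed direction under another choice of probe set, and 1 of the 8, Sulf2, passed the threshold in the opposite direction. Depth is not a property of these arrays; signal over background limits dim genes, whose log2 change falls as the offset grows, by the construction of the offset. For the other changes below the cause was not tested.

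The labels do not say whether the replicate numbers pair the arrays. Correlations of deviations for arrays of the same number were -0.059, 0.031 and 0.017. Those of the other pairs between groups ran from -0.098 to 0.083. No pairing was seen, but so few values cannot exclude it. With the replicate block, which costs residual degrees of freedom, 3216 genes passed (1657 higher, 1559 lower), 3070 of them also among the 5333, and myoblast fusion had adjusted p = 0.0738, the only list call the block changed. With an offset of 16, 467 genes changed at least 2-fold (258 higher, 209 lower). Tested probe set by probe set, which tests more features, 3942 were lower and 1801 changed at least 2-fold (1012 higher, 789 lower). An adjusted p under 0.01 left 2833 genes (1437 higher, 1396 lower), and a test against 1.5-fold left 613, of which 330 were higher. Leaving out single arrays gave 1841 to 2475 higher genes against 2821, with 1841 without 5AC replicate 1.

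With an estimated correlation none of the 14 list calls held. The estimate was below the preset 0.01 for germline genes (-0.016), p53 targets (0.0065), histone genes (-0.060), neuronal markers (-0.013) and interferon response (-0.0091). It was above 0.01 for the other lists called, up to 0.41 for mitosis. For the lists below 0.01 a higher correlation did not end the call. What that setting also changes is camera's degrees of freedom, which are fewer for every list. For the lists above 0.01 these effects were not separated. Adjusted p was 0.0706 for germline genes and p53 targets, 0.0926 for cholesterol synthesis, S phase, ribosome biogenesis, glycolysis, histone genes, neuronal markers and interferon response, 0.182 for mitosis and sarcomere, 0.197 for oxidative stress and 0.333 for extracellular matrix and myoblast fusion. The other 13 calls held under the remaining alternatives. Of lists not called, osteoblast and epithelial markers and the insulin-like growth factor pathway passed with the mean of probe sets. Osteoblast markers also passed with quantile normalization, array weights or without replicate 3 of either group. With fry, which does not compare a list with the other genes, 18 of the lists not called passed. Myoblast fusion, at 0.0410, had adjusted p = 0.0622 with quantile normalization, 0.177 with the mean of probe sets, 0.266 with probe sets without a suffix, 0.0554 with an offset of 16, and 0.0202 to 0.0746 with single arrays left out; the call was lost without untreated replicate 1 or 2 and without 5AC replicate 1 or 2 (0.0646, 0.0746, 0.0573 and 0.0737).

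Of the 5333 changed genes, 3344 were also called with the mean of a gene's probe sets, and 4663 when probe sets without a suffix were preferred. With the mean of a gene's probe sets the log2 change of Ctsl was 0.035 and of Cd53 -0.15. With probe sets without a suffix, that of Sbsn was 1.01, Ctsl 0.61, Man2b1 0.47, Idh2 0.12, Cdca3 0.27, Sulf2 -0.57 and Myh1 -0.25. The share of higher among changed genes was 52.9%, 55.5% with quantile normalization and 50.0% with median centring.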

Other observations

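Several genes outside the rule for named genes, picked here after their values were seen, also rose. Rbm43 went from an intensity of 15.1 to 172.8 in 5AC, the small leucine-rich proteoglycan gene Aspn from 9.64 to 117.5, the synaptonemal complex gene Syce2 from 13.4 to 148.4 and Mageb16 from 5.53 to 113.0 (n = 3 arrays each). The inflammatory caspase genes Casp1 and Casp4, which lie next to each other, had log2 changes of 2.83 and 1.49 (1.19 and 1.12 with 16 added), and the homeobox genes Rhox5 and Rhox6 of 2.85 and 1.84 (2.44 and 0.59).

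The tests of the offset, of a shift of dim probe sets and of germline genes were chosen after the result was seen, as were the limits used for background and clear signal. Taking the median probe-set mean of 20.8 as background and 100 as clear signal, 23 genes rose from background and 2 fell to it (exact binomial p = 1.94e-05, two-sided). Among 6875 genes with a mean below background the median log2 change was 0.0026 (quartiles -0.32 and 0.35). That decides nothing about a general shift of dim probe sets, since the arrays had about the same median and that median is the background limit. Whether a scaling step had made the medians alike is not known. An offset of 16 also gave 23 and 2, but this decides nothing, since the limits are set on intensities that the offset does not move. Of 45 germline genes dim in untreated cells, 7 (15.6%) rose from background, against 16 of 6967 other dim genes (0.230%; Fisher's exact p = 6.25e-11, one-sided). Since germline genes had already been seen among the largest increases and methylation was not measured, this restates the pattern, and whether it comes from silenced genes losing methylation stays open.

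Genes higher at least 2-fold lay next to each other in 28 pairs among 18134 ordered genes, against a mean of 17.1 in 10000 shuffles (permutation p = 0.0084, one-sided). Without pairs whose symbols share a stem 20 pairs were left, against 15.7 (permutation p = 0.155), so related neighbouring genes, which may share probe sequence or regulation, could make up the excess. Lower genes also had an excess, 16 pairs against 7.78 (permutation p = 0.0048), and without shared stems 10 against 7.16, a ratio of 1.396 where that of higher genes was 1.28. Whether neighbours change together in either direction stays open: the criterion written beforehand counted a number within the shuffled 95th percentile (10 against 12) as evidence against it, and it was set aside after the values were seen. The reason is that it contradicts the other criterion written beforehand, which the ratio of 1.396 meets, and that the higher genes, at 20 against 22, lie within their own 95th percentile too.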
